A study of Homo sapiens with 496 samples.

How the data were processed

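The series held 496 arrays of 22277 probe sets each, measured on a human Affymetrix array. The values were used as the authors deposited them, and the labels named neither the normalization method nor the logarithm. The deposited values ran from 2.38 to 14.1 and were read as log2 signals for that reason. The array medians ran from 4.49 to 5.02, with a median of 4.82, and no further scaling was applied. No pair of arrays was identical (0 pairs), and all 496 arrays had another array of their own cell line as nearest neighbour. Per the labels, cells had been plated for a day before dasatinib in DMSO was added, and RNA was made with column kits and checked for integrity.

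Cell line, dose and time were read from the sample titles, and the cell line was used as the block. A probe set was assigned to a gene when the array annotation named exactly 1 symbol. This held for 19070 probe sets, whereas 1043 named several symbols and 2164 were absent from the annotation. Current symbols were found through the gene identifier for 19058 probe sets. Each of the resulting 11963 genes was represented by its probe set with the highest mean. The 25% of genes with the lowest mean, under a log2 level of 3.88, was left out, which kept 8972 genes. Among the kept genes, 3769 had several probe sets.

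For each dose and time, the 0 nM value of the same line and time was subtracted, and a limma fit tested the mean within-line difference against 0 in either direction. Genes were called at a Benjamini-Hochberg adjusted p under 0.05 over all 8972 genes. The same fit tested 2000 against 100 nM, differences of the 2000 nM change between times, and 24 against 2 h at 0 nM. An F test in limma compared the 24 h change at 2000 nM between tissues with at least 3 lines, and a further limma fit compared leukemia with all other lines. Gene lists fixed before the data were examined (26 lists) were tested with camera at its preset correlation of 0.01, adjusted over the lists, and again with an estimated correlation and with fry. Counts of called list members were made over all genes and adjusted over the list alone. Correlations across lines used 100000 permutations and tested both directions.

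Genes were named by a fixed rule. For each 2000 nM comparison with 0 nM these were the 10 largest mean rises and the 10 largest mean falls among called genes that moved the same way in at least 2 of every 3 lines. The other comparisons named 5 of each. The F test named the 10 largest F values, leukemia the called genes with the largest differences, and each list up to 4 called members with the largest change. Y-linked genes and XIST were never named. In K-562, each list median was ranked among 10000 random lists matched on mean expression.

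The fits were tested on simulated data, normal noise with the spread of each of the 8972 genes and known changes in 200 of them. At 2000 nM and 2 h, 92% of genes shifted by 0.25 and 100% of genes shifted by 0.5 were recovered, with a false share of 4.48% among calls. At 2000 nM and 24 h the shares were 84% and 99%, with 7.58% false, and at 100 nM and 24 h they were 86% and 99%, with 6.09% false. The leukemia comparison recovered 35% of genes shifted by 0.5 and 98% of those shifted by 1.5, and the tissue test 22% and 98%. In simulated data for 2000 nM and 24 h, camera called 1 of 26 lists, the one shifted by 0.2. Genes were drawn independently of one another there, so this could not test camera on genes that are correlated.

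The alternatives for the values were the mean of all probe sets of a gene, no filter, a stricter filter leaving out 50% of genes, arrays centred on their median, and quantile normalization. Those for the fits were only the 47 lines with all 9 arrays, no leukemia lines, a trended robust variance, a fit without the block, all 3 doses in 1 fit, and each line left out in turn. An array counted as doubtful when its upper quartile lay more than 5 median absolute deviations under the median of all arrays, or its 3-prime minus 5-prime signal of the GAPDH or ACTB control probe sets lay as far above it (27 arrays). Leaving these out was added later. In 100 splits the signs or labels of the lines were permuted. The 62 control probe sets served only these checks. Probe sets without a single symbol were left out of the gene comparisons. The software was R 4.3.3 with the packages limma 3.58.1 and data.table version 1.17.8, and Python 3.11.15 with matplotlib 3.10.9 and numpy 2.4.6, with seed 1.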

Results

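The samples were 58 established human tumor cell lines of the NCI-60 panel, a reference collection from 9 tissues, treated with dasatinib, an inhibitor of SRC family, ABL, KIT and ephrin receptor kinases. The stated design was to compare transcriptional responses over time. Each line had at most 1 array per dose and time. At 0 nM there were 57 arrays at 2 h, 56 at 6 h and 54 at 24 h, at 100 nM 55, 58 and 52, and at 2000 nM 56, 58 and 50. Values below are mean differences within lines on the log2 scale with the SE over lines, and the base of the deposited logarithm was read from the values. The p-values measure the spread between lines, with 1 array each, and the labels did not say whether the arrays of a line came from separate cultures. The number of arrays limited the precision.

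The first question was what 2000 nM dasatinib had changed after 2 h. Among 8972 genes, 472 rose and 780 fell, and most changes were small, with 13 rises and 30 falls of at least 0.5. The deepest falls were in targets of YAP, a growth regulator controlled by adhesion and the cytoskeleton. The secreted matrix proteins CCN1 and CCN2 fell by 1.46 ± 0.16 (SE, n = 55 lines, lower in 51, adjusted p = 5.19e-10) and by 1.36 ± 0.13 (lower in 50, adjusted p = 2.51e-11). Transcription factor genes among the deepest falls included JUN at −1.04 ± 0.13 (lower in 46 of 55 lines), EGR1 at −1.05 ± 0.21 (41) and FOSL1 at −0.87 ± 0.11 (50). The gene of the receptor tyrosine kinase EPHA2, itself a dasatinib target, fell by 0.79 ± 0.10 (48). The largest rise was that of the orphan nuclear receptor NR4A2, by 2.07 ± 0.21 (higher in 52 lines, adjusted p = 9.10e-11). RGS2, a brake on G-protein signalling, rose by 1.13 ± 0.14 (49 lines) and the mTORC1 inhibitor gene DDIT4 by 1.03 ± 0.13 (49). NR4A3 rose by 0.93 ± 0.15 (44) and CCNG2, a cyclin linked to cell cycle exit, by 0.90 ± 0.11 (49).

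By gene group at 2000 nM and 2 h, YAP and TEAD targets fell in 9 of 20 measured members with 11 not passing. Adjusted over the list alone 10 fell and 2 rose (camera adjusted p = 2.83e-06). TGF-beta and SMAD targets fell in 5 of 11 (7 adjusted over the list alone, camera adjusted p = 5.95e-06). The pathway inhibitor SMAD7 fell by 0.79 ± 0.09 and ID1 fell by 0.54 ± 0.08. FOXO targets rose in 5 of 16 and none fell (8 adjusted over the list alone, camera adjusted p = 1.24e-06). The cyclin-dependent kinase inhibitor CDKN1B rose by 0.48 ± 0.06 (50 of 55 lines) and PDK4 by 0.35 ± 0.07 (43). Genes of G2/M and mitosis rose in 13 of 24 and none fell (16 adjusted over the list alone, camera adjusted p = 1.98e-10). The amounts were small, such as 0.22 ± 0.03 for the mitotic kinase gene AURKA (50 lines). These 4 lists were also called with an estimated correlation, at adjusted p values of 0.0197, 0.0197, 0.0301 and 0.0197 in this order.

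The MAPK output list fell in 9 of 19 at 2 h and 2000 nM with 0 up (11 adjusted over the list alone, camera adjusted p = 6.06e-07, but adjusted p = 0.123 with an estimated correlation). Its members IER3, MAFF and EPHA2 fell, IER3 by 0.72 ± 0.11. The list of MYC and ribosome biogenesis fell in 5 of 13 (also 5 adjusted over the list alone), at camera adjusted p = 0.00178 and adjusted p = 0.158 with an estimated correlation. MYC fell by 0.61 ± 0.10 (lower in 46 of 55 lines). STAT5 and BCR-ABL output had 5 members down and 1 up of 14 (7 down and 1 up adjusted over the list alone, camera adjusted p = 0.00282, adjusted p = 0.123 with an estimated correlation). DUSP6, a feedback phosphatase of ERK, fell by 0.67. The called members of this list with the largest changes were EGR1, DUSP6, MYC and ID1. These also belong to the immediate-early, MAPK, MYC and TGF-beta lists, so the lists are not independent results. NF-kB and inflammatory genes fell in 6 of 17, the same adjusted over the list alone (camera adjusted p = 0.00126, adjusted p = 0.160 with an estimated correlation, and 0.0665 with 50% of genes left out). The range over the alternatives was 2.29e-04 to 0.160, and the chemokine gene CXCL8 fell by 0.83 ± 0.14. ATF4 and unfolded protein response genes rose in 6 of 19 with 1 down, and adjusted over the list alone 11 rose and 2 fell (camera adjusted p = 6.46e-04, adjusted p = 0.107 with an estimated correlation). Interferon-stimulated genes rose in 5 of 20, the same adjusted over the list alone, at a camera adjusted p of 0.0471, which was 0.177 with an estimated correlation and 0.101 with quantile normalization. Over the alternatives it ran from 0.00584 to 0.177. Immediate-early genes split, with 4 up and 7 down of 17 both over all genes and adjusted over the list alone, and were not called as a group (camera adjusted p = 0.0917). Nor were the p53 list (1 up, 5 down of 14, camera adjusted p = 0.0917) or that of G1/S (1 up, 6 down of 24, camera adjusted p = 0.233). In the latter CCNE2 fell by 0.42 ± 0.05 (lower in 50 of 55 lines).

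The test behind these counts was a limma fit on differences within lines. A fit without the block called 2 genes in place of 1252. The share of called genes that rose was 37.7%, against 51.6% after centring arrays on their median (712 up, 667 down) and 49.3% after quantile normalization (629 up, 646 down).

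At 100 nM and 2 h, asked in the same way, 101 genes rose and 262 fell, with 5 rises and 7 falls of at least 0.5. NR4A2 rose by 1.23 ± 0.14 (SE, n = 55 lines, higher in 51), DDIT4 by 0.64 ± 0.09 (49) and CCNG2 by 0.60 ± 0.08 (46). EGR1 fell by 0.87 ± 0.10 (lower in 48 lines), CCN1 by 0.79 ± 0.13 (47), CCN2 by 0.75 ± 0.09 (50) and FOSL1 by 0.62 ± 0.07 (52). FOXO targets rose in 5 of 16 (7 adjusted over the list alone) and remained called with an estimated correlation (camera adjusted p = 8.74e-09 and adjusted p = 0.00916). MAPK output genes fell in 10 of 19, the same adjusted over the list alone (camera adjusted p = 2.72e-11, adjusted p = 0.0614 with an estimated correlation). YAP and TEAD targets had 7 down and 1 up of 20 in both counts, also adjusted over the list alone (camera adjusted p = 1.31e-04, adjusted p = 0.0614 with an estimated correlation). None of the 24 genes of G2/M was called (0 up, 0 down). Without the block, limma called 0 genes (32 at an unadjusted p under 0.05), and the YAP list had an adjusted p of 0.358 in a range of 1.24e-05 to 0.358 over the alternatives.

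After 6 h at 2000 nM, 1881 genes rose and 1111 fell, with 59 rises and 77 falls of at least 0.5. CCN2 fell by 1.78 ± 0.15 (SE, n = 56 lines, lower in 52, adjusted p = 3.78e-14), CCN1 by 1.56 ± 0.15 (51) and JUN by 1.15 ± 0.13 (48). The cytokine receptor gene TNFRSF12A fell by 1.10 ± 0.10 (53 lines), the matrix protein gene THBS1 by 1.04 ± 0.12 (49) and EPHA2 by 1.02 ± 0.12 (47). NR4A2 rose by 1.94 ± 0.20 (51 lines), DDIT4 by 1.35 ± 0.14 (49), the cAMP-responsive gene CREM by 1.25 ± 0.12 (52) and MAP2K6, a kinase upstream of p38, by 1.20 ± 0.11 (54). CTH, an enzyme of cysteine synthesis, rose by 1.15 ± 0.11 (53 lines) and the sterol regulator INSIG1 by 0.91 ± 0.07 (54, adjusted p = 1.51e-15).

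In the groups at 6 h and 2000 nM, YAP and TEAD targets fell in 11 of 20 (12 adjusted over the list alone). Of 17 lists called, this was the 1 also called with an estimated correlation (camera adjusted p = 9.75e-09 and adjusted p = 0.0175). MAPK output had 11 members down and 1 up of 19 (12 and 1 adjusted over the list alone, camera adjusted p = 3.55e-08). CCND1, the cyclin that links growth factors to the cell cycle, fell by 1.00 ± 0.12 (lower in 52 of 56 lines). Genes of MYC and ribosome biogenesis fell in 10 of 13, the same adjusted over the list alone (camera adjusted p = 9.75e-09), with NOP16 at −0.62 ± 0.08. For both lists the adjusted p was 0.0914 with an estimated correlation. ATF4 and unfolded protein response genes rose in 15 of 19 with 1 down, the same adjusted over the list alone (camera adjusted p = 8.87e-07, adjusted p = 0.0914 with an estimated correlation). The cystine transporter gene SLC7A11 rose by 0.74 ± 0.08 (higher in 53 lines). Cholesterol and SREBP genes rose in 9 of 16, and adjusted over the list alone 11 rose and 1 fell (camera adjusted p = 2.93e-05, adjusted p = 0.0914 with an estimated correlation). The synthesis enzyme genes MSMO1 and IDI1 rose by 0.35 ± 0.06 (48 lines) and 0.35 ± 0.05 (47). Lysosome and autophagy genes rose in 14 of 19 (15 adjusted over the list alone, camera adjusted p = 9.36e-06, adjusted p = 0.135 with an estimated correlation). GABARAPL1 rose by 0.71 ± 0.09 (higher in 53 lines). FOXO targets rose in 11 of 16 (12 adjusted over the list alone, camera adjusted p = 3.97e-05, adjusted p = 0.0914 with an estimated correlation). CDKN1B rose by 0.54 ± 0.05 and CDKN1C, another cyclin-dependent kinase inhibitor, by 0.81 ± 0.16.

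The cell cycle genes moved apart at 6 h and 2000 nM. G2/M and mitosis genes rose in 16 of 24 with 0 down (17 adjusted over the list alone, camera adjusted p = 8.87e-07, adjusted p = 0.201 with an estimated correlation). The spindle checkpoint kinase TTK rose by 0.33 ± 0.04 (higher in 50 of 56 lines). Genes of G1/S and DNA replication had 8 down and 1 up of 24, the same adjusted over the list alone (camera adjusted p = 8.80e-04, adjusted p = 0.318 with an estimated correlation). CCNE2 fell by 0.68 ± 0.09 (lower in 51 lines). SRF and MRTF cytoskeletal targets fell in 9 of 20 (10 adjusted over the list alone, camera adjusted p = 7.47e-04, adjusted p = 0.201 with an estimated correlation). SRF fell by 0.36 ± 0.05. TGF-beta and SMAD targets had 6 down and 1 up of 11 and NF-kB genes 7 down and 1 up of 17, each the same adjusted over the list alone (camera adjusted p = 8.73e-04 and 8.58e-05). Both had an adjusted p of 0.0914 with an estimated correlation. STAT5 and BCR-ABL output had 7 down and 1 up of 14, the same adjusted over the list alone (camera adjusted p = 3.37e-04, adjusted p = 0.0674 with an estimated correlation). Its largest changes included EGR1, DUSP6 and MYC, which also belong to other lists. Interferon-stimulated genes rose in 9 of 20, the same adjusted over the list alone (camera adjusted p = 7.20e-04, adjusted p = 0.148 with an estimated correlation). IFIT1 rose by 0.61 ± 0.11 (higher in 44 lines). Immediate-early genes (4 up, 8 down of 17) and adhesion and extracellular matrix genes (0 up, 5 down of 22), each the same adjusted over the list alone, were called at 0.0141 and 0.0212. They stood at adjusted p of 0.124 and 0.121 without the doubtful arrays, and at 0.0914 and 0.212 with an estimated correlation. Over the alternatives these ran from 1.83e-04 to 0.124 and from 0.0135 to 0.212. NRF2 targets (7 up, 1 down of 13, and 8 up, 1 down adjusted over the list alone) were called at 0.0316. This was 0.0671 with 50% of genes left out, and an adjusted p of 0.212 with an estimated correlation.

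The limma fit at 6 h and 2000 nM used differences within 56 lines. Without the block it called 99 genes in place of 2992 and the interferon and NRF2 lists had adjusted p of 0.224 and 0.421, the highest of ranges that began at 1.77e-06 and 1.66e-05. Doubtful arrays numbered 5 at 0 nM, 2 at 100 nM and 3 at 2000 nM at this time. Without them 1925 genes rose and 1866 fell, a share up of 50.8% against 62.9% with them.

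At 100 nM and 6 h, 1258 genes rose and 736 fell. NR4A2 rose by 0.90 ± 0.11 (SE, n = 56 lines, higher in 49), CCNG2 by 0.80 ± 0.09 (51) and CREM by 0.70 ± 0.07 (55). CCN2 fell by 1.24 ± 0.12 (lower in 51), CCN1 by 1.10 ± 0.12 (52), FOSL1 by 0.79 ± 0.10 (48) and CCND1 by 0.61 ± 0.07 (49). YAP and TEAD targets fell in 11 of 20 (13 adjusted over the list alone, camera adjusted p = 1.69e-10, adjusted p = 0.00866 with an estimated correlation). Genes of MYC and ribosome biogenesis fell in 9 of 13, the same adjusted over the list alone (camera adjusted p = 2.22e-10). MAPK output had 10 down and 1 up of 19 (11 and 1 adjusted over the list alone, camera adjusted p = 3.15e-09), and both lists had an adjusted p of 0.0806 with an estimated correlation. Lysosome and autophagy genes rose in 14 of 19 (16 adjusted over the list alone, camera adjusted p = 6.66e-08). FOXO targets rose in 11 of 16 (12 adjusted over the list alone, camera adjusted p = 1.13e-05), and both lists had an adjusted p of 0.0975 with an estimated correlation. G2/M genes rose in 12 of 24 (13 adjusted over the list alone, camera adjusted p = 2.03e-05, adjusted p = 0.382 with an estimated correlation). Cholesterol genes, with 0 up and 4 down of 16, were not called (camera adjusted p = 0.0822). Without the block limma called 0 genes in place of 1994 (244 at an unadjusted p under 0.05), and without the doubtful arrays 1385 genes rose and 1511 fell, a share up of 47.8% against 63.1%.

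**Figure D1:**
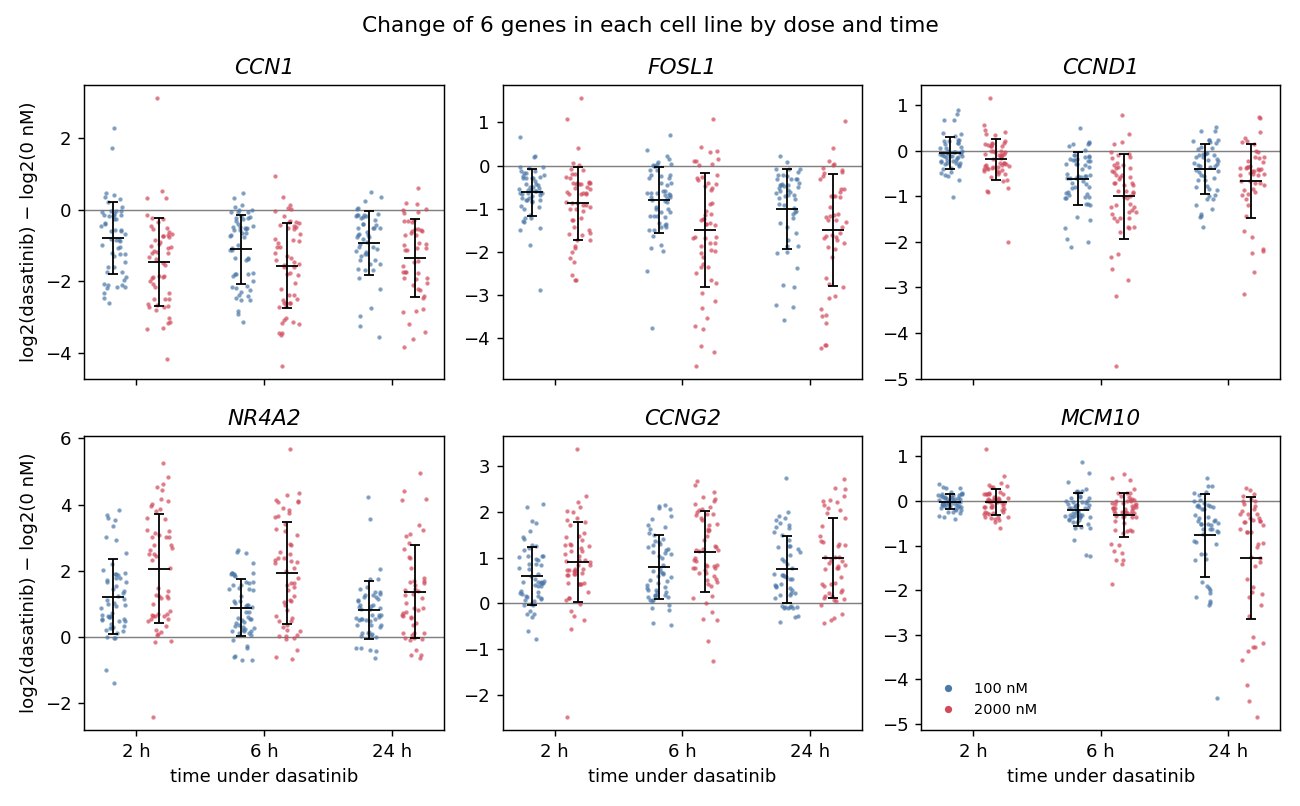
Each point is 1 cell line, the y axis is the log2 difference between dasatinib and 0 nM, the x axis is the time in hours, blue is 100 nM and red is 2000 nM, and black bars are the mean and SD over lines. CCN1 and NR4A2 had moved at 2 h, by −1.46 and 2.07 at 2000 nM, whereas MCM10 was lower at 24 h, by −1.29.

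After 24 h at 2000 nM, 2239 genes rose and 2539 fell, with 206 rises and 318 falls of at least 0.5. Genes of DNA replication and mitosis were now among the deepest falls. The replication factor MCM10 fell by 1.29 ± 0.19 (SE, n = 49 lines, lower in 42) and the origin licensing gene CDC6 by 1.20 ± 0.19 (43). The cyclin gene CCNE2 fell by 1.17 ± 0.16 (46) and the cytokinesis motor gene KIF23 by 1.02 ± 0.16 (44). CRY1, a repressor of the circadian clock, fell by 1.18 ± 0.09 (lower in 49 of 49 lines, adjusted p = 5.05e-14). FOSL1 was lower by −1.49 ± 0.18 (44 lines), CCN2 by −1.48 ± 0.17 (42) and CCN1 by −1.34 ± 0.15 (45). NR4A2 rose by 1.38 ± 0.19 (41 lines) and MAP2K6 by 1.36 ± 0.12 (47). The steroid and prostaglandin reductase gene AKR1C3 rose by 1.25 ± 0.21 (41), the prostaglandin synthase gene PTGES by 1.25 ± 0.22 (41) and CDKN1C by 1.11 ± 0.20 (36).

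In the groups at 24 h and 2000 nM, 24 of 24 genes of G1/S and DNA replication and 24 of 24 of G2/M and mitosis fell, the same adjusted over the list alone (camera adjusted p = 7.16e-11 and 1.86e-10). The mean of either list was lower in 46 of 49 lines, by −0.72 ± 0.11 for G1/S and −0.77 ± 0.13 for G2/M. With an estimated correlation their adjusted p was 0.339 and 0.352. Lysosome and autophagy genes rose in 14 of 19, the same adjusted over the list alone (camera adjusted p = 7.21e-07, adjusted p = 0.308 with an estimated correlation). The acid ceramidase gene ASAH1 rose by 0.70 ± 0.08 (46 lines) and the sialidase gene NEU1 by 0.70 ± 0.10 (42). FOXO targets rose in 15 of 16 (16 adjusted over the list alone, camera adjusted p = 6.19e-06, adjusted p = 0.339 with an estimated correlation). CCNG2 rose by 0.99 ± 0.12 (44 lines). Interferon-stimulated genes had 14 up and 1 down of 20, the same adjusted over the list alone (camera adjusted p = 5.61e-05, adjusted p = 0.339 with an estimated correlation). ISG20 rose by 0.91 ± 0.13 (40 lines) and IFI35 by 0.66 ± 0.08 (47). Genes of MYC and ribosome biogenesis fell in 12 of 13, the same adjusted over the list alone (camera adjusted p = 2.14e-06, adjusted p = 0.339 with an estimated correlation). NOP16 fell by 0.67 ± 0.09. YAP and TEAD targets fell in 14 of 20, the same adjusted over the list alone (camera adjusted p = 3.37e-04, adjusted p = 0.308 with an estimated correlation). The receptor kinase gene AXL fell by 0.86 ± 0.14 (43 lines). Heat shock genes fell in 8 of 9, the same adjusted over the list alone (camera adjusted p = 8.23e-04, adjusted p = 0.339 with an estimated correlation). HSPH1 fell by 0.41 ± 0.06 (42 lines). SRF and MRTF targets fell in 13 of 20, the same adjusted over the list alone (camera adjusted p = 0.00443, adjusted p = 0.368 with an estimated correlation). ACTN1 fell by 0.48 ± 0.06 (41 lines).

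Of the weaker groups at 24 h and 2000 nM, NRF2 targets had 6 up and 1 down of 13, the same adjusted over the list alone (camera adjusted p = 0.0355, adjusted p = 0.368 with an estimated correlation). NQO1 rose by 0.46 ± 0.07. Cholesterol genes had 8 up and 1 down of 16 (9 and 1 adjusted over the list alone) and ATF4 genes 11 up and 3 down of 19, the same adjusted over the list alone, both called at 0.0355. Neither was called with an estimated correlation (adjusted p = 0.636 and 0.352) or without doubtful arrays (0.0559 and 0.0595), and over the alternatives they ran from 0.0178 to 0.636 and from 3.62e-05 to 0.352. MAPK output had 2 up and 8 down of 19 and was no longer called (camera adjusted p = 0.152), while CCND1 was still lower, by −0.66 ± 0.11 (42 lines). Epithelial markers had 8 up and 1 down of 13 (camera adjusted p = 0.134), with JUP at 0.75 ± 0.12 and CDH1 at 0.45 ± 0.12. Adhesion genes had 1 up and 10 down of 22 (camera adjusted p = 0.108). The dasatinib target kinases had 0 up and 4 down of 16 (camera adjusted p = 0.419), with EPHA2 at −0.93 ± 0.10 and ABL2 at −0.33 ± 0.05. Housekeeping genes had 2 up and 4 down of 11 (camera adjusted p = 0.545), with HPRT1 at −0.37 ± 0.06. The remaining lists were not called, with 3 up and 6 down of 15 hypoxia genes and 3 up and 2 down of 14 p53 targets. They included 0 up and 2 down of 11 mesenchymal and neural, 1 up and 0 down of 8 melanocyte and 0 up and 1 down of 6 haematopoietic markers.

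The limma fit at 24 h and 2000 nM used 49 lines. Without the block it called 950 genes in place of 4778, and the YAP, SRF and NRF2 lists had adjusted p of 0.0737, 0.310 and 0.221. Over the alternatives these ran from 1.40e-10 to 0.308, from 5.75e-06 to 0.368 and from 9.36e-05 to 0.368.

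At 100 nM and 24 h, 2171 genes rose and 2152 fell, with 64 rises and 59 falls of at least 0.5. FOSL1 fell by 1.00 ± 0.12 (SE, n = 51 lines, lower in 49), CCN2 by 0.94 ± 0.11 (45), CCN1 by 0.93 ± 0.12 (46) and MCM10 by 0.77 ± 0.12 (44). BDH2, an enzyme of ketone body metabolism, rose by 0.76 ± 0.08 (46 lines) and CCNG2 by 0.74 ± 0.10 (40). Again 24 of 24 genes of G1/S and 24 of 24 of G2/M fell, the same adjusted over the list alone (camera adjusted p = 2.80e-11 and 4.34e-12), with an adjusted p of 0.277 for both with an estimated correlation. Interferon-stimulated genes rose in 18 of 20, the same adjusted over the list alone (camera adjusted p = 1.38e-06). Lysosome genes rose in 14 of 19 (15 adjusted over the list alone, camera adjusted p = 4.43e-06) and FOXO targets in 13 of 16 (14 adjusted over the list alone, camera adjusted p = 6.42e-06). Genes of MYC and ribosome biogenesis fell in 12 of 13 (13 adjusted over the list alone, camera adjusted p = 6.66e-08) and YAP targets in 15 of 20, the same adjusted over the list alone (camera adjusted p = 6.42e-06). These 5 lists each had an adjusted p of 0.171 with an estimated correlation. Dropping the block, limma called 150 genes in place of 4323 and the YAP list had an adjusted p of 0.105 (range over the alternatives 2.72e-10 to 0.171). After centring arrays on their median 1676 genes rose and 2809 fell, a share up of 37.4% against 50.2%.

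**Figure D2:**
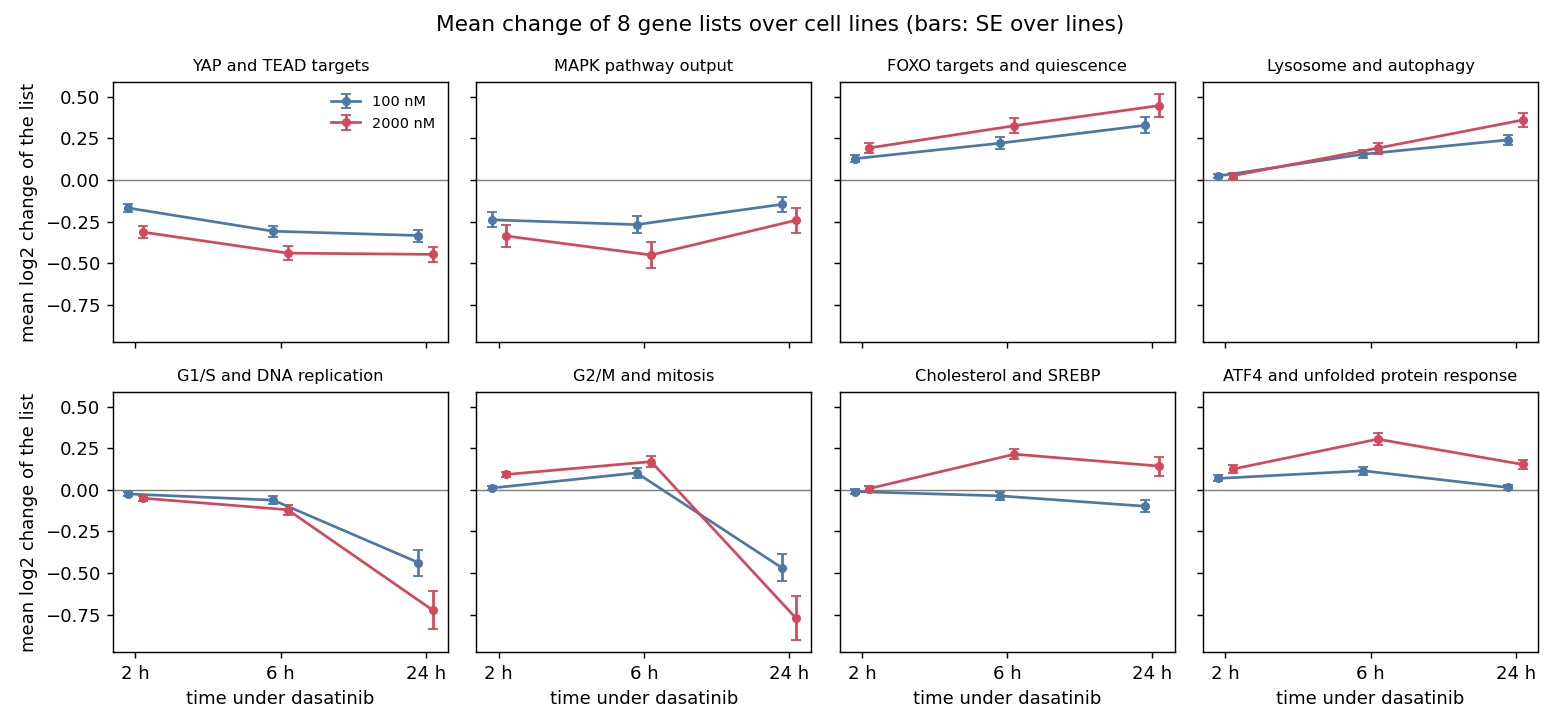
The y axis is the mean log2 change of all measured genes of a list and the x axis the time in hours, with points for the mean over lines, bars for the SE over lines, blue for 100 nM and red for 2000 nM. The G2/M list lay at 0.17 after 6 h and at −0.77 after 24 h at 2000 nM, and the YAP list was below 0 at each time.

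Where both doses were compared with the same 0 nM arrays, their changes correlated across genes at r = 0.789 at 2 h, 0.908 at 6 h and 0.955 at 24 h. The covariances were 0.00513, 0.0160 and 0.0385, and genes are not independent replicates. In 100 simulations in which only the shared 0 nM arrays linked the doses, r averaged 0.512, 0.642 and 0.717 and the covariance 7.63e-04, 0.00130 and 0.00229. With separate lines for either dose, r was 0.544, 0.753 and 0.850. Genes called up at both doses numbered 73 at 2 h, 1060 at 6 h and 1850 at 24 h. In 100 simulations with as many top genes per dose and only the 0 nM arrays shared, 35.3, 745 and 1269 genes overlapped on average (highest 55, 946 and 1555). Those down at both doses numbered 642 at 6 h (360 simulated on average, highest 500) and 1979 at 24 h (1363, highest 1669), and 0, 3 and 0 went opposite ways at 2, 6 and 24 h.

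Direct comparison of 2000 with 100 nM asked which genes changed with dose. At 2 h, 75 genes were higher and 193 lower at 2000 nM. NR4A2 was higher by 0.87 ± 0.13 (SE, n = 54 lines, 43 of them higher), and CCN1 was lower by −0.71 ± 0.07 (51 lines, adjusted p = 4.01e-10) and SMAD7 by −0.61 ± 0.06 (48). TGF-beta and SMAD targets were lower in 8 of 11, the same adjusted over the list alone (camera adjusted p = 1.48e-13, adjusted p = 6.89e-06 with an estimated correlation). ID1 was lower by −0.49 ± 0.07 and SMAD6 by −0.37 ± 0.05. G2/M genes were higher in 8 of 24 (16 adjusted over the list alone, camera adjusted p = 1.47e-13, adjusted p = 8.94e-04 with an estimated correlation). YAP targets were lower in 6 of 20, the same adjusted over the list alone (camera adjusted p = 8.18e-07, adjusted p = 0.0179 with an estimated correlation). Without the block limma called 0 genes in place of 268 (38 at an unadjusted p under 0.05). The share higher at 2000 nM was 39.2% after centring (107 up, 166 down) and 48.1% after quantile normalization (141 up, 152 down).

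At 6 h, 559 genes were higher and 375 lower at 2000 than at 100 nM. Cholesterol genes separated the doses, higher in 12 of 16 (14 adjusted over the list alone, camera adjusted p = 2.11e-19, adjusted p = 9.34e-04 with an estimated correlation). INSIG1 was higher by 0.77 ± 0.06 (SE, n = 58 lines, 55 of them higher, adjusted p = 5.28e-15), MSMO1 by 0.56 ± 0.06 (53) and the synthase gene HMGCS1 by 0.42 ± 0.07 (46). ATF4 genes were higher in 13 of 19 with 1 lower (15 and 1 adjusted over the list alone, camera adjusted p = 1.06e-12, adjusted p = 0.0148 with an estimated correlation). DDIT4 was higher by 0.56 ± 0.09 and the asparagine synthetase gene ASNS by 0.35 ± 0.05. TGF-beta and SMAD targets were lower in 8 of 11, the same adjusted over the list alone (camera adjusted p = 7.24e-11, adjusted p = 2.07e-04 with an estimated correlation). ID1 was lower by −0.53 ± 0.08. The clock repressors CRY1 and PER2 were lower by −0.57 ± 0.04 (55 lines, adjusted p = 8.88e-18) and −0.62 ± 0.08 (51). Without the block limma called 0 genes in place of 934 (41 at an unadjusted p under 0.05), and 398 with all doses in 1 fit. Without the doubtful arrays 581 were higher and 625 lower, a share higher of 48.2% against 59.9%.

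At 24 h, 593 genes were higher and 1196 lower at 2000 than at 100 nM. CRY1 was lower by −0.84 ± 0.07 (SE, n = 49 lines, 48 of them lower, adjusted p = 1.09e-13), CCNE2 by −0.63 ± 0.11 (41), and MAP2K6 higher by 0.80 ± 0.08 (47). Cholesterol genes were higher in 15 of 16, the same adjusted over the list alone (camera adjusted p = 3.97e-14, adjusted p = 0.0435 with an estimated correlation). The desaturase gene SCD was higher by 0.43 ± 0.08. Lysosome genes were higher in 9 of 19 (10 adjusted over the list alone, camera adjusted p = 2.62e-09, adjusted p = 0.0107 with an estimated correlation). ATF4 genes were higher in 12 of 19, and adjusted over the list alone 12 were higher and 2 lower (camera adjusted p = 6.24e-07, adjusted p = 0.0393 with an estimated correlation). Genes of G2/M were lower in 24 of 24, the same adjusted over the list alone, and of G1/S in 22 of 24 (23 adjusted over the list alone). Their camera adjusted p was 1.01e-13 and 3.55e-17, with adjusted p of 0.144 and 0.0780 with an estimated correlation. In a fit without the block limma called 0 genes in place of 1789 (32 at an unadjusted p under 0.05), and 850 with all doses in 1 fit.

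The response over time at 2000 nM was compared within lines. Between 2 and 6 h it differed for 1867 genes, 1215 toward higher and 652 toward lower values (n = 54 lines). MAP2K6 gained 1.04 ± 0.11 (SE, 49 lines) and CREM 0.84 ± 0.09 (48), while CCND1 moved by −0.78 ± 0.09 (48), TNFRSF12A by −0.70 ± 0.10 (47) and CRY1 by −0.65 ± 0.06 (51). Lower at 6 than at 2 h were 9 of 13 genes of MYC and ribosome biogenesis, the same adjusted over the list alone (camera adjusted p = 7.32e-09, adjusted p = 0.0200 with an estimated correlation). So were 7 of 20 SRF targets (9 adjusted over the list alone, camera adjusted p = 8.04e-06, adjusted p = 0.0399 with an estimated correlation). Higher were 11 of 16 cholesterol genes, the same adjusted over the list alone, and 11 of 19 lysosome genes (13 adjusted over the list alone). Their camera adjusted p was 8.52e-07 and 9.55e-07, and 0.0452 for both with an estimated correlation. Fitted without the block, limma called 0 genes (114 at an unadjusted p under 0.05), and the lysosome list had an adjusted p of 0.0692 (range over the alternatives 5.73e-09 to 0.0692). The share toward higher values was 65.1%, against 49.8% after centring (915 up, 923 down), 50.4% after quantile normalization (982 up, 965 down) and 54.8% without doubtful arrays (928 up, 765 down).

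Between 6 and 24 h at 2000 nM, the response differed for 2789 genes, 951 toward higher and 1838 toward lower values (n = 48 lines). Mitotic genes moved most, with the checkpoint kinase gene BUB1 at −1.21 ± 0.17 (SE, 44 lines) and the kinetochore motor gene CENPE at −1.17 ± 0.15 (46). The G2/M list was lower at 24 h in 24 of 24 genes, the same adjusted over the list alone (camera adjusted p = 2.36e-22). The G1/S list was lower in 23 of 24, the same adjusted over the list alone (camera adjusted p = 3.71e-15). Early falls were smaller at 24 h for MAPK output, with 6 of 19 genes toward higher values, the same adjusted over the list alone, and DUSP6 at 0.53 ± 0.10 (camera adjusted p = 0.00248). NF-kB genes also moved toward higher values, in 9 of 17 (11 adjusted over the list alone, camera adjusted p = 1.27e-04). Not every NF-kB gene showed a smaller fall. At 24 h IL6 and IL1B stood above 0 nM, by 0.48 and 0.30, while TRAF1 and NFKB1 stood below it, by −0.23 and −0.15. These 4 lists had an adjusted p of 0.151 with an estimated correlation. Dropping the block, limma called 161 genes, and after quantile normalization 1298 genes moved up and 1468 down, a share up of 46.9% against 34.1%. Genes called at both 6 and 24 h against 0 nM numbered 1231 up (469 by chance) and 880 down (314), and at both 2 and 6 h 259 up (99.0) and 423 down (96.6).

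As background, the 0 nM arrays were compared between 24 and 2 h. There 2192 genes rose and 1563 fell (n = 54 lines). DDIT4 rose by 1.07 ± 0.12 (SE, higher in 51 lines) and the metabolic enzyme gene IDH1 by 0.62 ± 0.05 (52). CCN2 fell by 0.78 ± 0.11 (lower in 46), MAFF by 0.77 ± 0.10 (45) and ATF3 by 0.74 ± 0.10 (45). Without drug, YAP targets fell in 12 of 20, and adjusted over the list alone 12 fell and 1 rose (camera adjusted p = 5.01e-04, adjusted p = 0.286 with an estimated correlation). TGF-beta and SMAD targets fell in 9 of 11, the same adjusted over the list alone (camera adjusted p = 5.14e-05, adjusted p = 0.0795 with an estimated correlation). Genes of G1/S fell in 13 of 24 and cholesterol genes rose in 12 of 16, each the same adjusted over the list alone (camera adjusted p = 5.14e-05 and 2.70e-04, adjusted p = 0.309 and 0.288 with an estimated correlation). Dropping the block, limma called 86 genes in place of 3755, and the YAP list had an adjusted p of 0.125 (range over the alternatives 1.87e-06 to 0.286).

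K-562, a chronic myeloid leukemia line that carries the BCR-ABL fusion kinase, had arrays at all doses only at 2 h, 1 per dose, so no test over replicates was possible. Its STAT5 and BCR-ABL output list had a median of −0.52 at 100 nM and −0.70 at 2000 nM, with 13 and 11 of 14 members lower. Each median was at percentile 0 of 10000 random lists. By list mean (−0.68 and −0.79), 2 and 4 of 55 lines were lower still, with K-562 itself counted among the 55. Named after their values were seen, the STAT5 targets PIM1 and CISH were at −1.23 and −0.55 at 100 nM and at −1.87 and −1.42 at 2000 nM, and MYC was at −0.99 and −0.91. The MAPK list had medians of −0.56 and −0.41 (percentile 0 at both doses), with the feedback inhibitor gene SPRY2 at −1.41 and −1.87. By MAPK list mean, 8 and 20 of 55 lines were lower than K-562, so its fall at 2000 nM did not stand out among lines. The YAP list had medians of −0.14 and 0.05, and at 2000 nM 53 of 55 lines had a lower list mean than K-562 (0.08). At 100 nM 26 of 55 lines had a lower YAP list mean than K-562 (−0.17).

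Tissues were compared by the 24 h change at 2000 nM. The size of the response, the root mean square of the log2 changes over genes, averaged 0.657 ± 0.149 (SD, n = 6) in renal lines, 0.554 ± 0.184 (n = 7) in ovarian lines and 0.342 ± 0.112 (n = 4) in leukemia lines. It differed between tissues (F = 3.31, permutation p = 0.00763, 47 lines). The G2/M list averaged −1.77 ± 1.38 (SD) in renal and −1.03 ± 1.24 in ovarian lines, −0.15 ± 0.15 in colon and 0.03 ± 0.18 in leukemia lines. It also differed (F = 2.70, permutation p = 0.0245, adjusted p = 0.0327 over 4 lists). The G1/S and MAPK lists also differed (permutation p = 0.0127 and 0.0156, both adjusted to 0.0311) and the YAP list did not (permutation p = 0.122). By limma, 881 genes differed between tissues. The annexin gene ANXA1 averaged −1.90 ± 0.89 (SD, n = 8) in melanoma lines (limma adjusted p = 6.60e-05 for the tissues). The receptor gene GPRC5C averaged 1.98 ± 0.67 (n = 6) in renal lines (limma adjusted p = 6.60e-05) and the transcription factor gene CEBPD 2.78 ± 0.71 in renal lines (limma adjusted p = 3.40e-04). With only lines holding all 9 arrays, 405 genes differed.

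**Figure D3:**
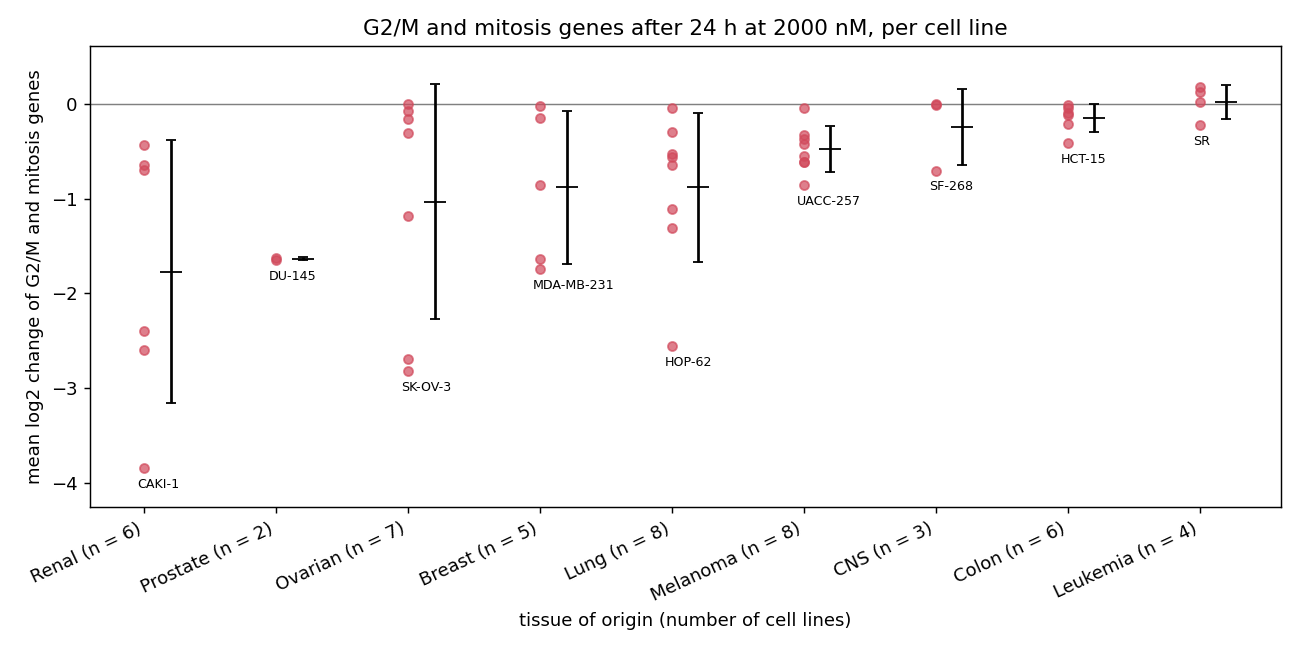
Each point is the mean log2 change of the G2/M list in 1 line after 24 h at 2000 nM (y axis) by tissue (x axis), with bars for the mean and SD over the lines of a tissue and the lowest line of each tissue named. CAKI-1, a renal line, was lowest at −3.85.

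The lines grouped under leukemia, which grow in suspension, were set against all others (4 against 45 lines) at 24 h and 2000 nM. The response of 3 genes differed (908 at an unadjusted p under 0.05), for each called gene toward higher values in leukemia lines. The keratin gene KRT18 differed by 1.33 ± 0.26 (SE, limma adjusted p = 0.0174) and ALOX5AP, needed for leukotriene synthesis, by 1.18 ± 0.18 (limma adjusted p = 2.02e-04). ANXA2 differed by 0.95 ± 0.19 (limma adjusted p = 0.0234). In the 45 other lines KRT18 averaged −0.30 ± 0.48 (SD). The leukemia values of KRT18 were 1.60 in HL-60, 1.78 in MOLT-4, 0.37 in RPMI-8226 and 0.36 in SR. In the same order of lines they were 2.17, 0.80, 0.09 and −0.08 for ANXA2 and 1.15, 0.29, 1.79 and 1.40 for ALOX5AP, so the 3 genes did not rise in the same lines. Leaving out HL-60 or MOLT-4 ended the calls of KRT18 and ANXA2, and ALOX5AP stayed called in each of 4 removals. Camera called 11 lists, led by G2/M with 0 of 24 genes called over all genes (camera adjusted p = 3.77e-12), and none (0) with an estimated correlation (adjusted p = 0.435 for G2/M). With only lines holding all 9 arrays 1 gene was called, with no filter 8, and without doubtful arrays 6.

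Across lines, 16 relations asked whether the early change or the starting level of a list went with the later fall of cell cycle genes at 2000 nM. Lines with a deeper fall of YAP targets at 6 h had a deeper fall of the G1/S list at 24 h (Pearson r = 0.452, Spearman rho = 0.548, n = 48 lines, permutation p = 0.00118, adjusted p = 0.00629). They also had a deeper fall of the G2/M list (r = 0.407, rho = 0.531, permutation p = 0.00390, adjusted p = 0.0125). Without the 2 farthest lines r was 0.438 and 0.384. Lines with a higher YAP list level at 0 nM also had a deeper fall of the G1/S list (r = −0.453, rho = −0.547, n = 49 lines, permutation p = 0.00109, adjusted p = 0.00629, and r = −0.430 without the 2 farthest). The YAP level with the G2/M list (r = −0.373, rho = −0.456, adjusted p = 0.0184) and the SRF level with the G1/S list (r = −0.380, rho = −0.457, adjusted p = 0.0184) passed too. Without leukemia lines they did not (r = −0.282 and −0.317, adjusted p = 0.120 and 0.0765). The MAPK change at 6 h correlated with the G1/S and G2/M changes at r = 0.452 and 0.494 (adjusted p = 0.00640 and 0.00629) and at rho = 0.355 and 0.411 (adjusted p = 0.0229 and 0.0108). It was weaker without the 2 farthest, both ovarian lines, where r was 0.248 and 0.334 and neither passed (adjusted p = 0.172 and 0.0710). The SRF change at 6 h passed with G1/S and G2/M by rank alone (rho = 0.381 and 0.384, adjusted p = 0.0148 and 0.0145). By r its adjusted p was 0.279 for both lists. The 2 lines farthest in this change, HOP-92 and HCT-116, had doubtful 0 nM arrays at 6 h. The SRF level with G2/M also passed by rank alone (rho = −0.393, adjusted p = 0.0123, against 0.0559 by r). No relation of the immediate-early list or of the MAPK level passed by either measure. The labels gave no batch within which to repeat the relations. The relations were not repeated within tissues either, although the G1/S and G2/M changes differed between tissues. Differences between tissues could therefore account for them, which was not tested.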

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

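The tests of handling, of low 0 nM arrays for the 8 genes, of epithelial RNA and of a single leukemia line by gene, the CREB and clock lists and the leaving out of doubtful arrays were chosen after the results were seen. Of 100 splits with permuted signs, the real one included, 1 had as many genes at 100 nM and 2 h (363 genes, highest other 0), at 2000 nM and 2 h (1252, other 0), at 100 nM and 6 h (1994, other 1) and at 2000 nM and 6 h (2992, other 0). It was also 1 of 100 splits at 100 nM and 24 h (4323, other 4) and at 2000 nM and 24 h (4778, other 0), so chance could be excluded. The same 1 of 100 splits held for 2000 against 100 nM at 2 h (268, other 0), 6 h (934, other 0) and 24 h (1789, other 1), and for 24 against 2 h at 0 nM (3755, other 12).

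The response at 2000 nM differed between 6 and 2 h for 1867 genes, and 1 of 100 splits reached that number (highest other 1). Values moved by 1.04 for MAP2K6, 0.84 for CREM, 0.75 for CSGALNACT1, 0.74 for CTH and 0.64 for INSIG1, and by −0.78 for CCND1, −0.70 for TNFRSF12A, −0.66 for NAV3, −0.65 for CRY1 and −0.65 for THBS1. Between 24 and 6 h it differed for 2789 genes, and 1 of 100 splits reached that (highest other 0). There the values moved by 0.77 for C1RL, 0.76 for PTGES, 0.75 for PLAAT4, 0.75 for CTSO and 0.72 for TM7SF2, and by −1.21 for BUB1, −1.17 for CENPE, −1.15 for CDCA3, −1.14 for KIF15 and −1.13 for SPC25.

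Between tissues, the 24 h response at 2000 nM differed for 881 genes, reached by 1 of 100 splits of the lines (highest other 182). The range of tissue means was 2.39 for ANXA1, 2.29 for GPRC5C, 1.54 for DOCK10, 1.05 for G3BP1, 1.45 for HPS4, 2.73 for CEBPD, 1.63 for THBS3, 1.98 for SLC6A6, 1.51 for PLIN2 and 0.73 for STARD7. Within 7 tissues, no line (0) stood apart from the others in response size. The probe sets without a single gene name, which no comparison of genes used, were looked at in part. Among 1713 of them, 199 were called at 2000 nM and 2 h, 425 at 6 h and 810 at 24 h.

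Genes of G2/M and mitosis were higher at 2 h and 6 h of 2000 nM, by a list mean of 0.0921 (44 of 55 lines) and 0.17 (45 of 56 lines), before their fall at 24 h. Arrays of low quality were not the whole cause, since without them the lower end of the 95% interval was 0.0707 at 2 h and 0.0804 at 6 h, where SNB-75, the highest line with 1.42, had a doubtful 0 nM array. Normalization between arrays was set against lower ends of 0.0691 and 0.0995 after quantile normalization, and low 0 nM arrays against lower ends of 0.0516 and 0.0315 for 2000 minus 100 nM. All were above 0, so none of these explains the rise as a whole. An early gathering of cells in G2 or mitosis may be the reason, a hypothesis for which the arrays hold no cell counts.

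The genes NR4A2, NR4A3, CREM, SIK1, PDE4B, PDE4D, RGS2 and GEM rose together, by a mean of 0.92 at 2 h (53 of 55 lines), 1.07 at 6 h (56 of 56) and 0.86 at 24 h (49 of 49) of 2000 nM. These 8 genes were grouped after their values had been seen, so their joint rise is no independent result. A general immediate-early response to handling was set against the other immediate-early genes, for which the higher of the upper ends at 2 and 6 h was −0.19. Members such as EGR1 and JUN had already been seen to fall under drug, which could hide a rise from handling. This test could therefore not exclude handling. Low 0 nM arrays would have left no difference between the doses, where the lower end for 2000 minus 100 nM at 6 h was 0.43. A candidate explanation is activity of CREB with its coactivators CRTC, which are held back by salt-inducible kinases. A textbook list of 10 further targets, not yet looked at, had a median of 0.11 and a percentile of 99.3 among random lists at 2000 nM and 6 h, with 5 of 10 called up. At 2 h the percentile was 96.3 at 100 nM with 2 of 10 called up, and 100 at 2000 nM with 1. At 100 nM and 6 h, where the 8 genes rose in 56 of 56 lines by a mean of 0.53, the further targets had a median of −7.12e-04 at percentile 32.1. At 24 h their percentiles were 91.9 at 100 nM and 94.4 at 2000 nM. For 2000 minus 100 nM they were 98.3, 99.3 and 100 at 2, 6 and 24 h, with 0, 3 and 2 called up. The support is uneven over doses and times, and the explanation stays open.

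In leukemia lines at 24 h of 2000 nM, 3 genes differed from other lines, KRT18 by 1.33, ALOX5AP by 1.18 and ANXA2 by 0.95. Chance could not be excluded, since 10 of 100 splits gave as many genes and the highest other gave 176, many times the real 3. Other splits may catch a structure among the lines, and what lies behind such counts was not tested. RNA or cells of an epithelial line would have raised other epithelial markers too, but the median of 12 of them in HL-60 and MOLT-4 was 0.0984 with an SE of 0.0680, far under the 1.60 and 1.78 of KRT18. Many of these markers started near background in these lines, where a small admixture may not show. The check did not cover RPMI-8226 and SR, where ALOX5AP rose most. A single leukemia line was not the source for ALOX5AP, which stayed called after each of 4 removals. For ANXA2, 2 leukemia lines, HL-60 at 2.17 and MOLT-4 at 0.80, lay above the highest of the 45 other lines (0.21). Its rise was thus not confined to a single line, but its call ended when HL-60 was left out. A single line could therefore not be excluded as the source of the ANXA2 call. For KRT18 the same 2 lines lay above the highest other line (0.73). However, the 0 nM level of KRT18 at 24 h was 3.36 in MOLT-4, against 7.35 in HL-60. The MOLT-4 level was under that at which dim genes were left out, so its rise started near background. A single line could therefore not be excluded for KRT18. The calls of KRT18 and ANXA2 ended without HL-60 and also without MOLT-4, so they do not stand for all lines grouped under leukemia. A response particular to blood cells stays open and untested.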

How the results depend on the processing

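The alternative without doubtful arrays was chosen after seeing the data. Of 11324 values of named genes under the alternatives, 10134 stayed called or stayed uncalled, 1148 lost the call, 36 gained it and 6 reversed. A reversed direction was counted only for values called in the main fit. For gene lists, of 4238 values 3900 stayed called or stayed uncalled, 238 lost the call, 99 gained it and 1 reversed. Directions of lists were not compared for the estimated correlation and fry. An estimated correlation between genes ended 129 of 153 list calls. In K-562, 234 of 256 list values stayed within the spread and 22 moved.

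Without the block on cell lines, differences between lines entered the error, and limma called 0 genes at 100 nM and 2 h, 2 at 2000 nM and 2 h, 0 at 100 nM and 6 h, 99 at 2000 nM and 6 h, 150 at 100 nM and 24 h and 950 at 2000 nM and 24 h. It called 0, 0 and 0 for 2000 against 100 nM, 0 for 6 against 2 h, 161 for 24 against 6 h and 86 for 24 against 2 h at 0 nM. Counts at an unadjusted p under 0.05 were 32, 244, 38, 41, 32 and 114 for those with 0, in this order. Unblocked values reversed for TNFRSF10B at 100 nM and 2 h (−0.12 to 0.00858), IFI27 (0.16 to −0.0388) and ID1 (0.20 to −0.0335) between 6 and 2 h, and MYOF between 24 and 6 h (−0.22 to 0.15). For the interferon list between 6 and 2 h, the direction given by camera, relative to all other genes, reversed. Its mean went from 0.11 to 0.00912 and stayed above 0. The mean of all probe sets reversed KLHL24 between 6 and 2 h (−0.15 to 0.24) and RAB27A at 0 nM (0.12 to −0.0559). With all doses in 1 fit, 2000 against 100 nM gave 398 genes at 6 h and 850 at 24 h. The cause was not tested.

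With only lines holding all 9 arrays, so fewer lines, 405 genes differed between tissues and 1 in leukemia. Leukemia gave 8 genes with no filter and 6 without doubtful arrays. Leaving out each leukemia line gave 1 to 8 genes, with 1 without HL-60, 3 without MOLT-4 (1 of them shared, ALOX5AP in both cases), 8 without RPMI-8226 and 6 without SR. Leaving out 1 line at a time gave 319 to 426 genes at 100 nM and 2 h, and 4644 to 4854 at 2000 nM and 24 h. Without the 2 farthest lines, the MAPK change correlated with G1/S at 0.248 (adjusted p = 0.172) and with G2/M at 0.334 (adjusted p = 0.0710), and the YAP level with G2/M at −0.321 (adjusted p = 0.0710). Without leukemia lines, the YAP level correlated with G2/M at −0.282 (adjusted p = 0.120) and the SRF level with G1/S at −0.317 (adjusted p = 0.0765). Signal near background limits dim genes, of which 25% were left out.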

Other observations

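The clock list was written, and its test chosen, after CRY1 and PER2 had been seen. At 2000 nM and 6 h, the clock repressors CRY1 and PER2 fell by 0.80 ± 0.05 (SE, n = 56 lines, lower in 55) and by 0.84 ± 0.12 (lower in 49). Chosen after their values were seen, the activator BMAL1 rose by 0.33 ± 0.06 (44 lines) and the clock output repressor NFIL3 by 0.62 ± 0.06 (51). Of 9 clock genes not looked at before, 2 rose, 3 fell and 4 passed no threshold, with a median of −0.0819 at percentile 1.90 of random lists, so the group did not move one way. At 100 nM and 2 h neither CRY1 nor PER2 was called, and 1 of the 9 rose. At 100 nM and 6 h both were called down, yet 4 of the 9 rose and 0 fell (median 0.12, percentile 99.6). At 100 nM and 24 h, 4 rose and 0 fell (percentile 95.9). At 2000 nM, 2 rose and 1 fell at 2 h (percentile 5.5), and 3 rose and 2 fell at 24 h (percentile 78.6). At 24 h CRY1 was lower by −1.18 ± 0.09 in 49 of 49 lines, whereas PER2 was lower by −0.28 ± 0.10 in 34 of 49.

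Genes of the hypoxia list went both ways at 2000 nM and 6 h, with 4 up and 4 down of 15. The glycolytic enzyme gene HK2 fell by 0.69 (lower in 50 of 56 lines) and the peptide hormone gene ADM by 0.65 ± 0.09 (46), while the stress gene NDRG1 rose by 0.56 ± 0.09 (43). The p53 list also had 4 up and 4 down of 14, with GADD45A at −0.42 ± 0.08 and the DNA repair gene DDB2 at 0.23 ± 0.05. Of the epithelial markers, 5 of 13 rose, among them the junction gene JUP by 0.36 ± 0.07 in 41 lines. None of these lists was called by camera.

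Some genes that fell under drug also fell with time at 0 nM. Across genes, the change at 0 nM between 2 and 24 h correlated with the change at 2000 nM and 6 h at r = 0.433, with 494 genes down in both (194 by chance) and 908 up in both (460), where genes are not independent replicates. A hypothesis is that adding medium with the dose stimulated the cells and that this faded, which may set the level from which early targets fell. It asked for a fall of the immediate-early list between 2 and 6 h at 0 nM, and the upper end of the 95% interval was −0.0347 (mean −0.0961, lower in 37 of 55 lines). The test could not show that medium was the stimulus.

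The ratio of 3-prime to 5-prime signal of control transcripts did not separate drug from 0 nM in any of 12 tests (lowest adjusted p = 0.968). Only for the 90 pairs of a gene and a dose comparison against 0 nM picked by the naming rule were other probe sets looked at singly. Of these pairs 45 had another probe set, and 0 had one moving the opposite way with a t beyond 3. Outside them, the mean of all probe sets reversed KLHL24 between 6 and 2 h and RAB27A at 0 nM, so probe sets of other genes did disagree.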
